A study of Mus musculus with 3 samples.

How the data were processed

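Total RNA of monocytes from the peripheral blood of adult C57BL/6J mice (5 to 6 weeks of age) was sequenced in 3 libraries, which the labels number as biological replicates 1, 2 and 3 of 1 group. Per the labels' protocols, 100 ng of RNA was depleted of ribosomal RNA and made into libraries with a ScriptSeq kit, which keeps the strand. Fragment sizes were recorded as 200 to 594 bp for library 1, 200 to 491 bp for library 2 and 200 to 1000 bp for library 3. The isolation protocol is named but its gate is not given in the sources used here. All 3 libraries carry the same donor record and no sex, so p-values measure the spread between these libraries, which may be partly technical.

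Per the accompanying notes, the authors quantified each library on assembly mm10 with GENCODE M21, and again with GENCODE M4, in both cases with spike-in and phiX sequences added. The deposited gene tables give an expected count per gene, the estimated number of reads, which is not whole where reads were divided among similar transcripts. The deposited TPM values, relative transcript abundances, were scaled by the authors to a fixed total over every row of a table, small RNAs included. A further deposited table per library, made from the reads on M21, gives an estimated count and TPM per transcript. The quantification programs and the strand setting of the counting are not given in the sources used here.

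The M21 gene tables were used for the values reported. They list 55536 genes beside 26248 numbered rows that name no gene and 96 spike-in rows; 55450 of the genes matched the GENCODE M21 annotation used for symbols, biotypes and coordinates (mm10). The M4 tables list 43346 genes, of which 42462 matched. Rows that name no gene held 0.000571%, 9.04e-05% and 7.53e-05% of the counts of libraries 1, 2 and 3. They stayed out of the tests but are part of the totals of counts and TPM. Also left out of the tests were 3471 genes with an effective length, the length by which TPM divides, of 0 in at least 1 library. Transcript counts summed per gene differed from the gene table by at most 0.03 counts. Expected counts were 27.2, 26.5 and 19.9 M in libraries 1, 2 and 3. For a transcript of 1000 bases, 1 TPM stood for 112, 121 and 76.0 counts. Where a gene had no counts, 3 counts were taken as the limit that a count of 0 allows; such limits cover counting error only, since duplicates made by PCR cannot be told from separate molecules.

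The series holds 1 group and no contrast, so each gene's level was set against a fixed level. Expected counts were rounded to whole numbers and fitted with edgeR 4.0.16 (glmQLFit, intercept only). The offset of each gene and library was the log of the count that 1 TPM stood for, which makes the quasi-likelihood F test a two-sided test of 1 TPM. Because the tool's own test function takes no design of a single column, F was computed from the deviances and the moderated dispersions of that fit. Genes with a summed count of 10 or more were tested, with Benjamini-Hochberg adjustment at 0.05. Simulated data for 17662 genes gave every gene the same coefficient of variation between libraries, 0.744. On these the fit called 2.45% of 2000 genes simulated at 1 TPM. It recovered 29% of 100 genes at 2 TPM, 81% at 4 TPM, 18% at 0.5 TPM and 72% at 0.25 TPM.

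Gene lists for monocytes, monocyte classes, other blood cells and general functions (24 lists, 278 genes, 277 of them matched) and all tests named so far were fixed before the data were examined. No gene stood in more than 1 list. For 10 contrasts of lists, the difference of mean log2(TPM + 0.1) between lists was taken within each library and given as the mean and SD of 3 libraries. An exact two-sided sign-flip test over libraries cannot give less than p = 0.25 here. Beside it stands a two-sided permutation of members between both lists (100000 draws, across genes, which are not replicates), adjusted over the 10 contrasts. The spread between libraries was summarised by the common dispersion of edgeR.

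The comparison of each list between libraries was added after the data were seen. It is the median log2 difference over members with a mean TPM of 1 or more, relative to the median protein-coding gene with a mean TPM of 1 or more. It is set against 10000 random lists of protein-coding genes matched on mean expression and describes these libraries only. The structural and nuclear noncoding RNAs were left out of that comparison, since too few protein-coding genes are as abundant. Tested on simulated data for lists of 10 among 8000 genes, 5.5% of 200 unshifted lists and 100% of 200 lists shifted by 1 (log2) fell outside the central 95% of random lists. The simulated changes were independent between genes. Members of a real list can change together, which places such lists outside that range more often, so the 5.5% need not hold for them. No adjustment was made over lists or pairs of libraries. Near-identical relatives of the named genes were searched with BLAST+ 2.17.0 (95% identity over 50% of the shorter transcript).

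Genes were named by a rule fixed beforehand. It takes the 10 protein-coding and 5 other genes with the highest mean TPM, the 3 highest members and the lowest member of each list, and Ly6c2, Ccr2, Csf1r, Nr4a1, Cx3cr1, Lyz2, Ly6g and Cd3e; some genes that the rule takes are not reported here. It also takes the 10 genes with the largest SD of log2(TPM + 0.1) between libraries among those with a mean TPM of 10 or more. Alternatives were the M4 tables, the tables made from the reads, limma 3.58.1 on log2(TPM + 0.1) and log2(TPM + 1), DESeq2 1.42.0, TMM factors, DESeq2 size factors, other count filters, levels of 0.5 and 2 TPM, TPM over protein-coding genes alone, other pseudocounts, the median of members, members with a mean TPM of 1 or more, and each library left out. Counts of list members were repeated with the M4 tables, at both other levels and with each library left out. Other steps used R 4.3.3, Python 3.11.15, scipy 1.17.1 and statsmodels 0.14.6.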

Results

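Total RNA-seq was recorded from 3 libraries of mouse blood monocytes, with 27.2, 26.5 and 19.9 M expected counts in libraries 1, 2 and 3. Counts above 0 were found for 16635, 16810 and 19160 of 55536 genes. Protein-coding genes held 76.2%, 75.7% and 78.2% of the counts but 10.9%, 9.84% and 10.7% of the TPM total. Small nuclear RNAs, short and abundant parts of the splicing machinery, took 60.8%, 60.0% and 60.5% of TPM but 7.56%, 9.25% and 5.14% of the counts. A level of 1 TPM in these tables therefore equals 9.17, 10.2 and 9.35 TPM on a scale of protein-coding genes alone.

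The most abundant protein-coding transcripts combined macrophage-lineage genes with genes of other blood cells. Hba-a2, an alpha globin, had the highest mean, 1593 TPM ± 1248 (SD, n = 3), followed by Lyz2, the lysozyme of myeloid cells, at 1135 TPM ± 376 (SD, n = 3), and the actin-binding Tmsb4x at 1076 TPM ± 164 (SD, n = 3). Gzma, a protease of cytotoxic granules, reached 626 TPM ± 341 (SD, n = 3). Actb, Eef1a1, Rps27 and the lipid carrier Apoe lay between 576 and 684 TPM, beside the mitochondrially encoded mt-Atp8 (761 TPM) and mt-Co1 (526 TPM). Of 17664 genes tested, 7639 lay above 1 TPM, 1124 below and 8901 on neither side (edgeR quasi-likelihood, adjusted p under the threshold of 0.05). Protein-coding genes, of which 12982 were tested, made up 7018 of the genes above and 782 of those below. The count below was 256 without library 1, 381 without library 2 and 1086 without library 3, while the count above was 7241 to 7559 with any library left out. On TPM over protein-coding genes alone, 12092 genes lay above and 1 below.

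The monocyte list was expressed nearly throughout, with 14 of 16 members above 1 TPM, also when adjusted over the list alone. Lyz2 (ENSMUSG00000069516.8, chromosome 10, 117277331 to 117282321, mm10) had 1448, 1238 and 718 TPM in libraries 1, 2 and 3. The lysosomal protease Ctss had 367 TPM ± 132 and the signalling adaptor Tyrobp 172 TPM ± 9.69 (SD, n = 3 each). Csf1r (ENSMUSG00000024621.16, chromosome 18, 61100598 to 61132149), the receptor of the growth factor that keeps monocytes alive, had 69.6 TPM ± 17.1 (SD, n = 3; edgeR adjusted p = 1.39e-13). Cd14, the lipopolysaccharide co-receptor, was the lowest member at 0.45, 1.40 and 1.44 TPM and was on neither side of 1 TPM (edgeR adjusted p = 0.783).

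Markers of non-classical monocytes, the patrolling class with little Ly6C on its surface, stood above those of classical, Ly6C-high monocytes in 3 of 3 libraries. All 12 non-classical members and 8 of 10 classical members lay above 1 TPM, and 1 classical member lay below it, with the same counts adjusted over each list alone. Spn (CD43) had 125 TPM ± 4.83, Nr4a1 (ENSMUSG00000023034.7, chromosome 15, 101254269 to 101274795), a transcription factor required for this class, 96.8 TPM ± 44.3, Cd36 76.3 TPM ± 30.8 and Cx3cr1 (ENSMUSG00000052336.7), the fractalkine receptor, 24.6 TPM ± 2.62 (SD, n = 3 each). Among classical markers Ifitm6 had 43.3 TPM ± 16.3 and Ccr2 (ENSMUSG00000049103.14), the chemokine receptor for leaving the marrow, 28.2 TPM ± 3.58 (SD, n = 3 each). Ly6c2 (ENSMUSG00000022584.14, chromosome 15, 75108158 to 75111970), which encodes the defining antigen and shares 98.3% identity over 70.5% of the shorter transcript with Ly6c1 (mean 0.0067 TPM), had 6.81, 7.72 and 24.7 TPM. Vcan, a proteoglycan, was at 0.020, 0.020 and 0.050 TPM and lay below 1 TPM (edgeR adjusted p = 0.00929), a call that was lost without library 3 (adjusted p = 0.0740).

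The classical list minus the non-classical list was -2.47, -2.47 and -2.57 in libraries 1, 2 and 3, a mean of -2.50 ± 0.06 (log2, SD, n = 3) or 5.67-fold. Both lists hold different genes and no reference population was measured, so this difference does not give the share of either class. Whether other cells held part of these transcripts was not tested. The exact sign-flip test over libraries gave p = 0.25, the smallest this design allows. Permuting members between both lists gave an adjusted p of 0.00898; with medians in place of means the difference was -1.96 and the adjusted permutation p 0.0543.

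Genes of natural killer cells were abundant in each library, with geometric means over the list of 33.7, 33.2 and 99.9 TPM in libraries 1, 2 and 3, beside 40.5, 37.0 and 32.8 TPM for the monocyte list. All 10 NK members lay above 1 TPM, also when adjusted over the list alone. Gzma had 484, 379 and 1014 TPM, Ncr1 (ENSMUSG00000062524.4, chromosome 7, 4337724 to 4345164), the activating receptor NKp46, 41.8, 39.8 and 133 TPM, and the lowest member Eomes, a transcription factor of this lineage, 5.04, 4.46 and 17.2 TPM in libraries 1, 2 and 3. Klra8, an NK receptor with 39.7, 48.4 and 110 TPM, shares 96.6% identity with the pseudogene Klra14-ps (mean 17.0 TPM), so its level is uncertain. The monocyte list minus the NK list was 0.26, 0.16 and -1.60, a mean of -0.39 ± 1.05 (log2, SD, n = 3; exact sign-flip p = 1; adjusted permutation p = 0.673). Without library 3 it was 0.21 (adjusted permutation p = 0.825).

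B cell genes were present at lower levels. Of 13 members 10 lay above 1 TPM and 11 when adjusted over the list alone. Ighm, the heavy chain of IgM, had 55.4 TPM ± 2.19, Cd79b 12.0 TPM ± 1.54 and Ms4a1 (CD20) 10.3 TPM ± 2.46 (SD, n = 3 each). Monocyte minus B cell markers was 2.95 ± 0.18 (log2, SD, n = 3), above 0 in 3 of 3 libraries (exact sign-flip p = 0.25; adjusted permutation p = 0.00183). T cell genes were lower, with 3 of 13 above and 3 below 1 TPM (3 and 2 adjusted over the list alone). The kinase Lck had 17.5, 11.5 and 42.5 TPM, while Cd28 had 2.46 TPM ± 0.343 and Cd3g 2.40 TPM ± 1.09 (SD, n = 3 each). Whether cells other than T cells held part of these transcripts was not tested. Cd3e (ENSMUSG00000032093.7), an invariant chain of the T cell receptor complex, was at 0.080, 0.030 and 0.16 TPM from 12, 4 and 16 counts. The call for Cd3g was lost without library 3 (edgeR adjusted p = 0.0619). Monocyte minus T cell markers was 5.86 ± 0.66 (log2, SD, n = 3), above 0 in 3 of 3 libraries (exact sign-flip p = 0.25; adjusted permutation p = 3.33e-05), and 3.36 with only members of a mean TPM of 1 or more (adjusted permutation p = 0.0396).

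Neutrophil markers were low beside monocyte markers, with list medians of 1.57, 1.32 and 0.20 TPM in libraries 1, 2 and 3. Ly6g (ENSMUSG00000022582.4), the antigen used to gate mouse neutrophils, had 0 counts in each library, which allows up to 0.0575, 0.0518 and 0.0870 TPM. Retnlg (ENSMUSG00000022651.6, chromosome 16, 48872621 to 48874496), a resistin-like protein of granulocytes, had 5839, 5972 and 0 counts, or 124, 114 and 0 TPM, where 0 counts allow up to 0.0970 TPM. Csf3r had 6.91 TPM ± 1.08 (SD, n = 3) and S100a8 5.53, 1.42 and 0.35 TPM. Of 11 members, 2 lay above 1 TPM and 0 below, also when adjusted over the list alone. The 2 above were Csf3r and Retnlg, and the call of Retnlg was lost with limma on log2(TPM + 0.1) (limma adjusted p = 0.1275). Above lay 5 without library 3, 4 with the M4 tables and 6 at a level of 0.5 TPM in place of 1. Granule proteins of neutrophil precursors, such as Ltf, Lcn2 and Ngp, had no member above 1 TPM of 8 (0 also adjusted over the list alone), with means up to 0.070 TPM. Of the basophil, eosinophil and mast cell list, 4 of 10 lay above and 1 below (the same adjusted over the list alone), and 2 above without library 2 and 7 without library 3. The eosinophil chemokine receptor Ccr3 had 12.4, 11.6 and 0.17 TPM, Ms4a2, a chain of the IgE receptor, 6.61, 5.98 and 2.35 TPM, and Epx, a granule peroxidase, 0 counts in each library. Ccr3 was called above 1 TPM, but not with limma on log2(TPM + 0.1) (limma adjusted p = 0.1689). Monocyte minus neutrophil markers was 4.70, 4.78 and 6.59 (mean 5.36 ± 1.07) and monocyte minus basophil, eosinophil and mast cell markers 4.78, 4.45 and 6.27 (mean 5.17 ± 0.97; log2, SD, n = 3). Both were above 0 in 3 of 3 libraries (exact sign-flip p = 0.25; adjusted permutation p = 5e-05 each).

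Red cell and platelet genes differed between library 3 and the other libraries. Hba-a2 (ENSMUSG00000069917.7, chromosome 11, 32296489 to 32297298) had 2338, 2289 and 152 TPM and Hbb-bs 799, 674 and 73.1 TPM in libraries 1, 2 and 3. Hba-a2 shares 99.8% identity with Hba-a1, so reads were divided between both copies. The platelet chemokine Ppbp (ENSMUSG00000029372.7) had 2.17, 2.47 and 33.7 TPM, the integrin Itga2b 8.64, 4.72 and 14.6 TPM and the platelet tubulin Tubb1 2.57, 1.26 and 23.3 TPM. Above 1 TPM lay 7 of 11 erythroid and 6 of 12 platelet members, with the same counts adjusted over each list alone and 1 erythroid member below by that adjustment. Without library 3, 4 platelet members lay above. Klf1, a transcription factor of red cell precursors, had 0 counts in each library. Monocyte minus erythroid markers was 1.31, 1.31 and 3.56, a mean of 2.06 ± 1.30 (log2, SD, n = 3; exact sign-flip p = 0.25; adjusted permutation p = 0.151), and 1.31 without library 3. With only members of a mean TPM of 1 or more it was 0.16 (adjusted permutation p = 0.899). Monocyte minus platelet markers was 5.95, 5.94 and 2.86, a mean of 4.92 ± 1.78 (log2, SD, n = 3; exact sign-flip p = 0.25; adjusted permutation p = 5e-05).

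Dendritic cell and tissue macrophage genes were low. Cd209a and Ccr7, with 2.46 TPM each, were the dendritic members above 1 TPM, and 3 of 10 lay below (2 and 4 adjusted over the list alone); Cd209a lost its call without library 1 (edgeR adjusted p = 0.0534). Adgre1 (F4/80), which blood monocytes also carry, had 30.4 TPM ± 10.1 (SD, n = 3) and was the 1 tissue macrophage member of 12 above 1 TPM, with 2 below (1 and 3 adjusted over the list alone). The scavenger receptor Cd163 was at 0.23 TPM ± 0.070 and Mrc1 at 0.293 TPM ± 0.246 (SD, n = 3 each); both lay below 1 TPM, and both calls were lost without library 2 (edgeR adjusted p = 0.0561 and 0.0829), that of Cd163 also without library 1 (0.0539). Monocyte minus dendritic cell markers was 6.24 ± 0.19 and monocyte minus tissue macrophage markers 7.47 ± 0.08 (log2, SD, n = 3), each above 0 in 3 of 3 libraries (exact sign-flip p = 0.25; adjusted permutation p = 3.33e-05 each). With only members of a mean TPM of 1 or more, which leaves Adgre1 alone among tissue macrophage genes, these were 4.21 and 0.33 (adjusted permutation p = 0.0257 and 0.899).

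**Figure D1:**
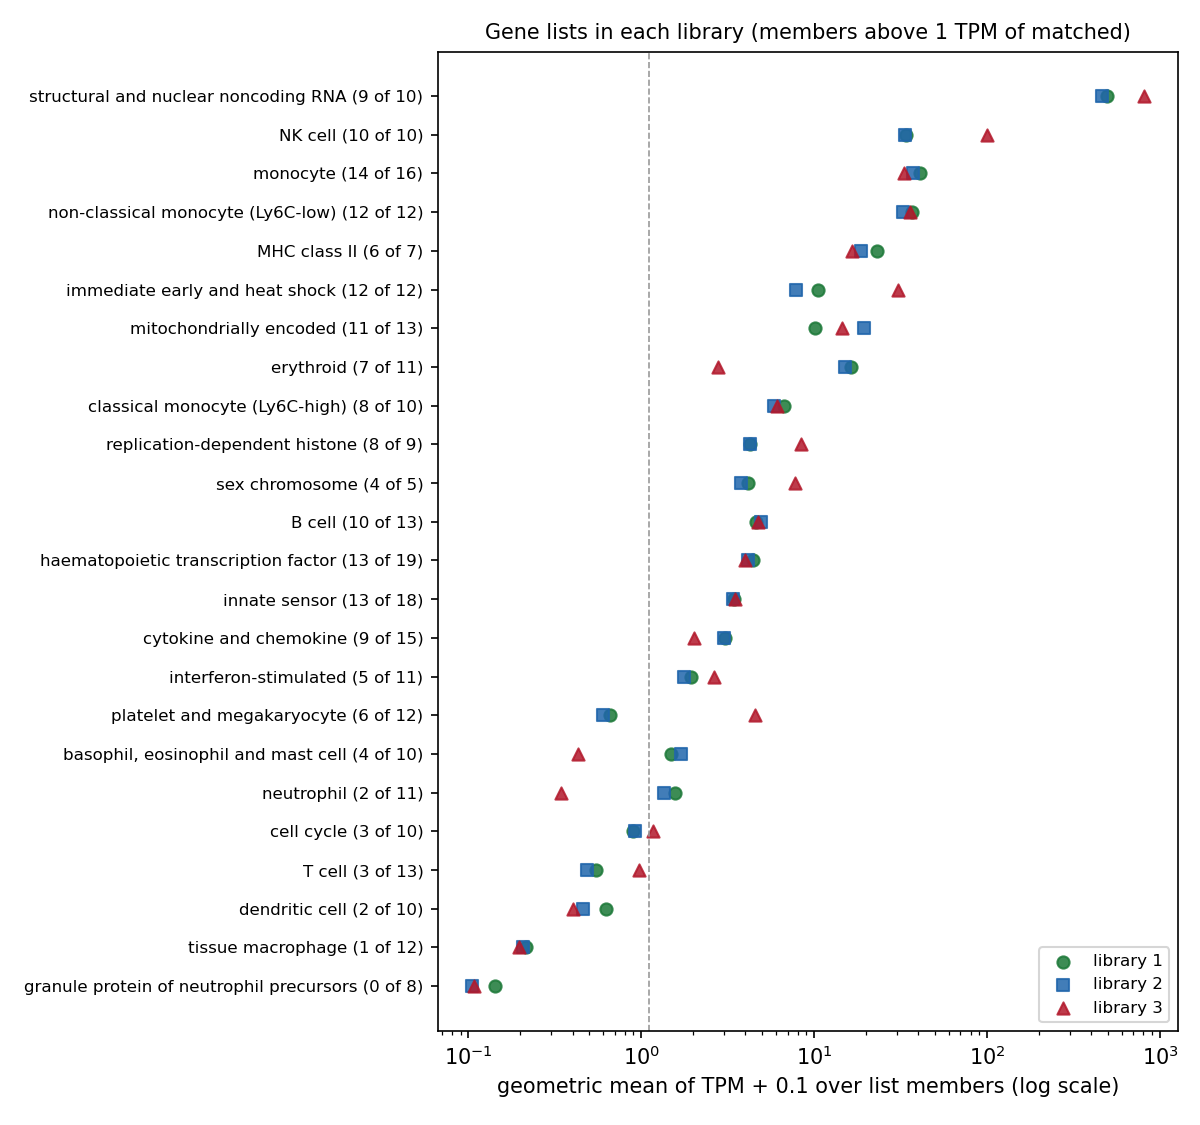
Geometric mean of TPM + 0.1 over the members of each of 24 gene lists (horizontal log axis), with points for libraries 1, 2 and 3 and, in brackets, the members above 1 TPM of those matched. NK cell genes stood near monocyte genes in libraries 1 and 2 and above them in library 3, while neutrophil granule and tissue macrophage genes were lowest; the dashed line marks a TPM of 1.

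Many genes of innate sensing and antigen presentation lay above 1 TPM, as did 7018 of the 12982 protein-coding genes tested. Whether any list exceeded that share was not tested. Of 18 innate sensors 13 lay above 1 TPM, led by Clec7a (48.4 TPM ± 6.89), a receptor for fungal glucans, Tlr13 (21.2 TPM ± 4.80) and Tlr7 (13.2 TPM ± 1.14; SD, n = 3 each), while Tlr5 was at 0.050, 0.050 and 0 TPM. Of 7 MHC class II genes 6 lay above, with Cd74 at 85.0 TPM ± 8.79, H2-Ab1 at 81.2 TPM ± 18.9 and H2-Eb1 at 54.5 TPM ± 12.2 (SD, n = 3 each), and the transactivator Ciita at 1.15 TPM ± 0.312. Cytokines and chemokines gave 9 of 15 above, led by Ccl6 (118, 124 and 24.2 TPM), Ccl4 (66.9 TPM ± 15.5) and Ccl3 (53.5 TPM ± 6.31), with Nos2 at 0 counts in each library. Of 19 haematopoietic transcription factors 13 lay above and 1 below, with Spi1 (PU.1) at 47.9 TPM ± 16.6, Cebpb at 39.0 TPM ± 13.5 and Irf8 at 30.3 TPM ± 10.2 (SD, n = 3 each). The 1 below was Tal1, a factor of red cell and megakaryocyte precursors, at 0.22 TPM ± 0.147, whose call was lost without library 1 or without library 2 (edgeR adjusted p = 0.0991 and 0.0553). The counts of these 4 lists were the same when adjusted over the list alone.

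Stress and growth programmes were uneven. All 12 immediate early and heat shock genes lay above 1 TPM, and 10 without library 3, with Btg2 at 45.1, 36.6 and 80.7 TPM, Junb at 46.6, 37.9 and 75.7 TPM and Jun at 14.8, 13.9 and 66.2 TPM. Interferon-stimulated genes gave 5 of 11 above (6 and 1 below when adjusted over the list alone), with Irf7 at 9.46 TPM ± 3.09 and Ifit1 at 0.277 TPM ± 0.190 (SD, n = 3 each). Cell cycle genes gave 3 of 10, Pcna at 27.1 TPM ± 6.43, Mcm5 at 3.85 TPM ± 1.64 and Top2a at 1.87 TPM ± 0.707 (SD, n = 3 each), and Ccnb1 was at 0.163 TPM; Top2a lost its call without library 3 (edgeR adjusted p = 0.0509). Replication-dependent histone genes gave 8 of 9 above, led by Hist1h1c at 67.5 TPM ± 10.9 (SD, n = 3). Mitochondrially encoded genes gave 11 of 13; mt-Co2 was listed at 0, 0.010 and 0 TPM, but its nuclear copy Gm28661, 100% identical over its whole length, at 339 TPM, so reads of these genes could have been placed on either copy. Of 10 structural and nuclear noncoding RNAs 9 lay above, with Rn7sk at 45670 TPM ± 14132 (SD, n = 3), and Kcnq1ot1 lay below. Counts adjusted over the list alone were the same for these lists except the interferon-stimulated genes.

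Outside protein-coding genes, the highest levels were those of Rnu2-10, Gm24950, Gm23971 and Gm23849, copies of the U2 spliceosomal RNA on chromosome 11 with an equal share of 75670 TPM ± 7631 each, and of Gm22513 at 59954 TPM ± 17441 (SD, n = 3 each). The 10 genes most variable between libraries were Retnlg and 9 small RNAs, each with a near-identical sequence in another gene: Rnu5g, Gm25313 and Gm25099, the U3 genes Rnu3b1 to Rnu3b4, Gm27505 and Snora16a. Rnu5g had 4811, 10923 and 0 TPM from 1708, 4572 and 0 counts, where 0 counts allow up to 21.2 TPM, and Rnu3b1 had 342, 834 and 0 TPM.

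Sex-linked genes gave 4 of 5 above 1 TPM (4 also adjusted over the list alone). The Y-linked Eif2s3y had 26.1, 31.6 and 16.9 TPM, Ddx3y 23.8, 20.9 and 13.8 TPM and Kdm5d 5.08, 3.75 and 4.61 TPM in libraries 1, 2 and 3. Xist (ENSMUSG00000086503.4, chromosome X, 103460366 to 103483254), the RNA that coats the inactive X, had 0, 0 and 4348 counts, or 0, 0 and 6.84 TPM, where 0 counts allow up to 0.0029 and 0.0026 TPM. It was on neither side of 1 TPM (edgeR adjusted p = 0.382).

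**Figure D2:**
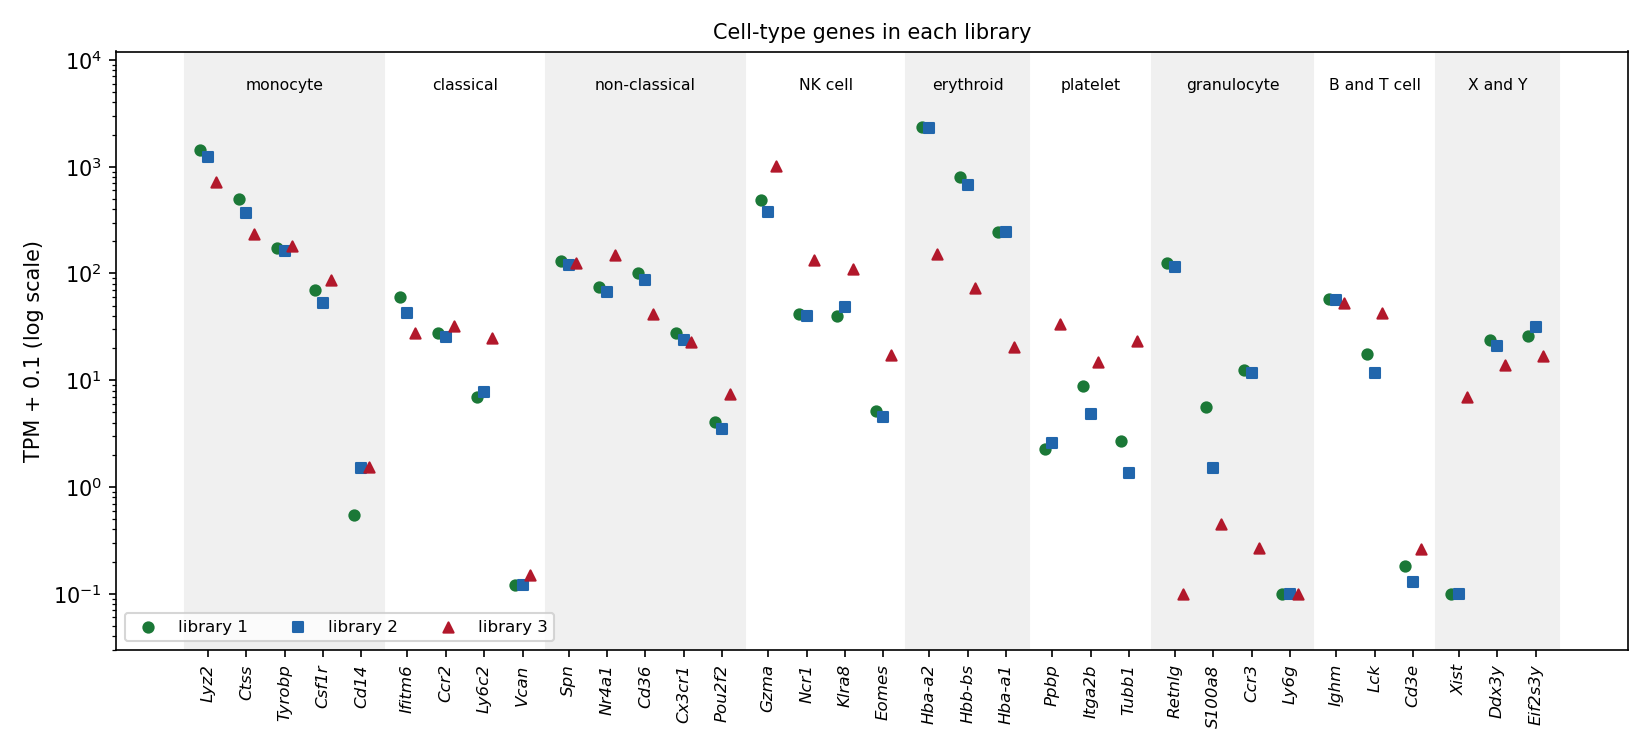
TPM + 0.1 (vertical log axis) of genes of monocytes, monocyte classes, other blood cells and the sex chromosomes, with points for libraries 1, 2 and 3. NK cell and platelet genes were highest and globin genes lowest in library 3, Retnlg had 0 TPM there, and Xist had 0 TPM in libraries 1 and 2.

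The libraries were also set against each other list by list, as a description with no replicate check. The median protein-coding gene differed by 0.21 (log2) between library 3 and library 1, by 0.37 between library 3 and library 2, and by -0.16 between library 2 and library 1, and lists are given relative to that shift. NK cell genes were higher in library 3 for 10 of 10 members, with a median of 1.45 over library 1 and 1.24 over library 2. Platelet genes were higher there for 8 of 8 members, by medians of 3.08 and 2.92, and erythroid genes lower for 8 of 8, by medians of -3.40 and -3.56. Basophil, eosinophil and mast cell genes were lower for 7 of 7 members (-2.49 and -2.11), and neutrophil genes had medians of -2.60 and -2.32; with a pseudocount of 1 the neutrophil medians were -1.43 and -1.35 and the former median against library 1 -1.41. Immediate early and heat shock genes were higher for 12 of 12 members (0.73 and 1.06), and cytokines and chemokines had medians of -0.98 and -1.14. Dendritic cell genes had medians of -1.44 and -1.47 over only 3 members (-0.96 against library 2 with a pseudocount of 1). Each of these medians lay outside the central 95% of random lists. In library 3 against library 1 alone, so did T cell (1.04, over only 4 members, Cd3e and Cd3d not among them) and MHC class II genes (-0.82). Histone genes (0.51, but 0.03 with the tables made from the reads) did so too. Against library 2 alone, so did mitochondrially encoded (-1.04, or -0.57 with correction for length and GC content), classical monocyte (-0.73, or -0.44 with the tables made from the reads), haematopoietic transcription factor (-0.69) and B cell genes (-0.44). Between library 2 and library 1 the NK cell, platelet and erythroid medians were 0.09, -0.06 and 0.02, at the percentiles 90.5, 26.5 and 66.1 of random lists. Other lists did differ between that pair. Mitochondrially encoded genes had a median of 0.63 in library 2 over library 1 (percentile 100), but single members ranged from 0.16 to 8.56. In library 3 over library 2 members of that list ranged from -8.77 to 8.85. Reads of these genes could have been placed on a nuclear copy, so both medians of this list may not be differences in expression. In library 2 over library 1, B cell genes had a median of 0.38 (percentile 99.5). T cell genes had 0.54 over 4 members (percentile 98.3, but 0.21 with the tables made from the reads). Immediate early and heat shock genes were lower in library 2 for 11 of 12 (median -0.23, percentile 1.03). Monocyte genes differed by -0.55 and -0.58 in library 3 against libraries 1 and 2 (percentiles 4.32 and 2.62) and non-classical genes by -0.19 and -0.32 (percentiles 64.5 and 35.6).

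**Figure D3:**
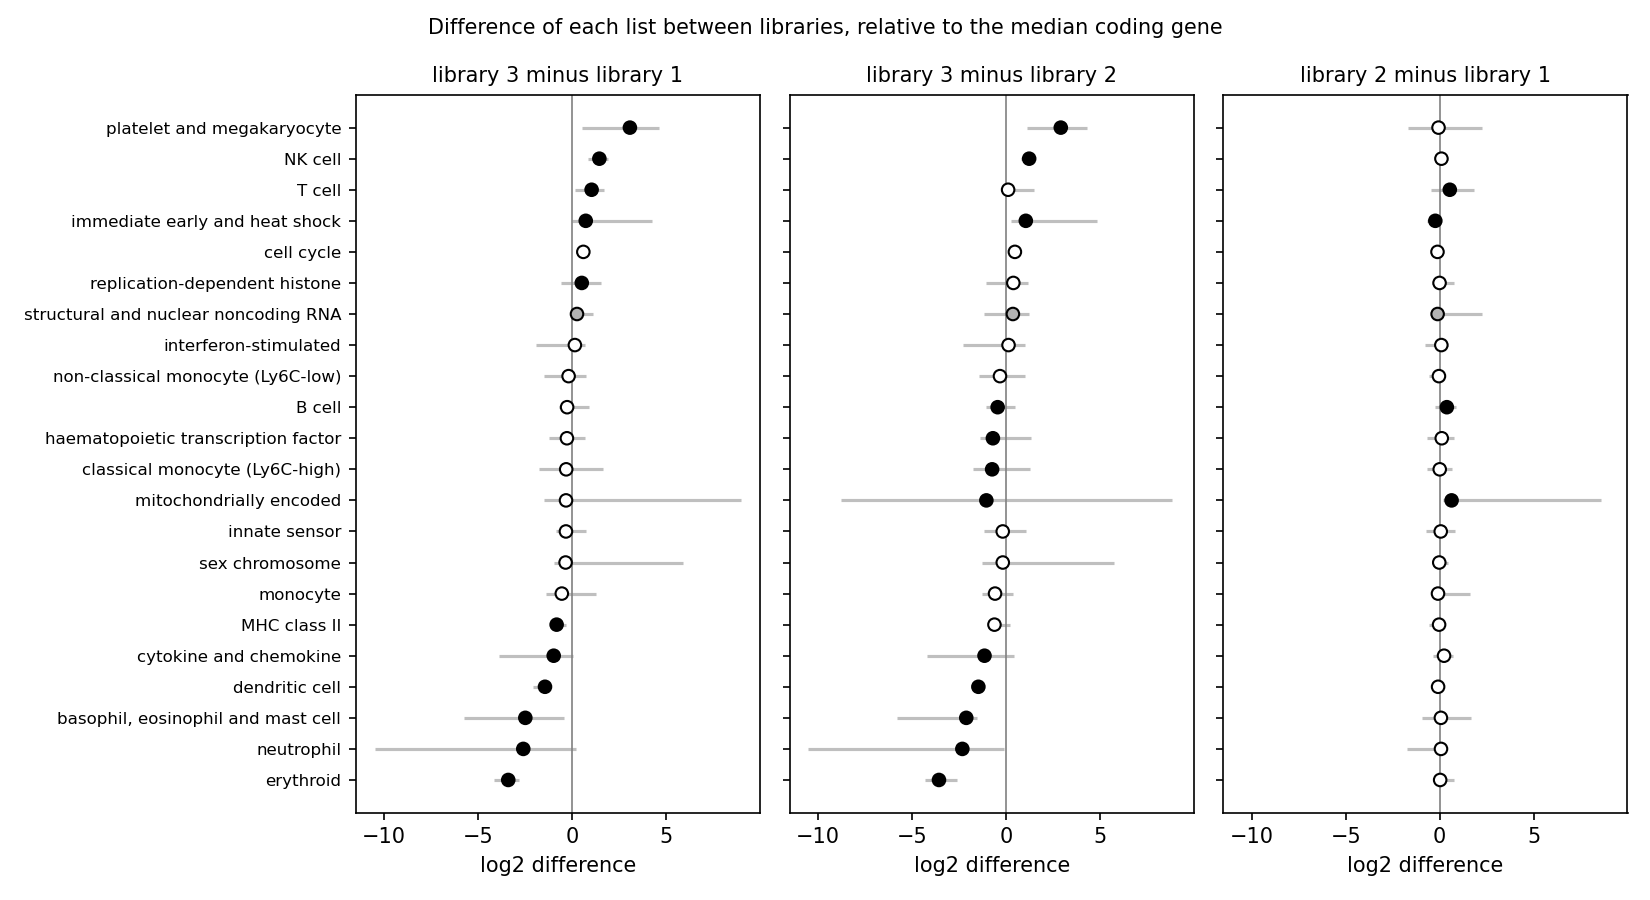
Median log2 difference of each gene list (circles) between libraries 3 and 1, 3 and 2, and 2 and 1, relative to the median protein-coding gene, with lines from the lowest to the highest member. Filled circles lie outside the central 95% of random lists matched on mean expression, and the grey circle was not compared with them. Platelet and NK cell lists stood highest and the erythroid list lowest in both comparisons with library 3.

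Across 8292 protein-coding genes with a mean TPM of 1 or more, which are not independent replicates, Pearson's r of log2(TPM + 0.1) was 0.942 between libraries 1 and 2, 0.895 between 1 and 3 and 0.892 between 2 and 3. The share of genes that differed by more than 2-fold from the median shift was 6.40%, 12.3% and 12.5% in the same order. The chi-square per gene was 28.4 for libraries 1 and 2, above counting error, so these tables do not hold the same reads; the value does not show that the samples were independent. The common biological coefficient of variation was 0.744 (edgeR).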

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

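The tests of explanations in this part were chosen after the results were seen, whereas the monocyte minus NK list contrast and the calls above 1 TPM were planned. Each library was a sample of 1 group, so no biological explanation set by the design was tested, and groups of 3 are too small for a test of outlying samples.

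Signal appeared on rows outside the gene measurement. Library 1 had 85 counts and library 2 had 16 counts on ERCC spike-in rows, and the numbered rows that name no gene held 70, 8 and 15 counts in libraries 1, 2 and 3. Each of these exceeds the 3 counts that a count of 0 allows. The 85 counts of library 1 fell on 4 spike-in sequences, chiefly ERCC-00171 (29 counts), ERCC-00002 (28) and ERCC-00130 (27).

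NK cell genes were abundant in all 3 libraries, near the monocyte list in libraries 1 and 2 and above it in library 3 (monocyte minus NK list 0.26, 0.16 and -1.60, log2). Reads shared with paralogs do not account for this, since 9 of the 9 list members without a near-identical relative lay above 1 TPM. Expression by the monocytes in a fixed ratio to their other genes is argued against for the level in library 3, where the change from library 1 was larger for the NK cell list than for the monocyte list by 2.00 ± 0.21 (log2, standard error over members), but stays open for libraries 1 and 2, between which the difference was 0.18 ± 0.13. NK cells among the collected cells are a candidate source. Members kept a close ratio to each other, with an SD of 0.32 (log2) over their changes from library 1 to library 3. That SD was at the 3.19 percentile of random lists (33.5 between libraries 2 and 1). Between libraries 1 and 3 the percentile was 0.61 for MHC class II genes, 20.7 for the erythroid list and 95.35 for the platelet list. A low SD therefore does not tell admixed cells from genes regulated together. The most abundant NK list member, Gzma, had 1014 TPM in library 3. The gate of the isolation is not known here, and NK genes switched on together within monocytes stay open.

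Erythroid and platelet transcripts moved in opposite directions between library 1 and library 3. A smaller share of monocytes alone would raise both, but the platelet median lay 6.47 ± 0.54 (log2, standard error over members) above the erythroid median. After the trend with transcript length was removed the gap was 6.48 ± 0.56, and after that with GC content 6.45 ± 0.55, which argues against either trend as the whole cause. Differing amounts of red cells and platelets carried into each library remain a candidate explanation that was not tested separately, as do differences in handling between the libraries.

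Xist was found in library 3 beside Y-linked genes in every library. Reads of the antisense gene Tsix do not account for it, since Tsix counts were 0.253% of Xist counts in library 3. Whether female cells lay beside male cells in library 3 cannot be told: the 4 Y-linked genes of the sex chromosome list had a median change of -0.59 (log2) from library 1 and -0.57 from library 2, at the percentiles 3.48 and 4.83 of random lists, but the monocyte list had -0.55 and -0.58. The changes were also uneven, for Ddx3y, Eif2s3y, Kdm5d and Uty -0.99, -0.83, -0.35 and -0.33 from library 1 and -0.96, -1.27, -0.08 and -0.17 from library 2. The labels record no sex, and reads carried over from another library stay open.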

How the results depend on the processing

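The genes above 1 TPM numbered 7040 to 7719 over the alternatives that kept this level, leaving aside the TPM of protein-coding genes alone. That scale gave 12092 because it is about 10 times higher. With levels of 0.5 and 2 TPM in place of 1, 9280 and 5742 genes lay above. The genes below 1 TPM changed more: 6290 with limma on log2(TPM + 0.1), 6737 with limma on log2(TPM + 1), 4114 with DESeq2, 176 at a level of 0.5 TPM, 3398 at 2 TPM, 1 with TPM over protein-coding genes, and 256 to 1086 with each library left out; the cause of the differences between tools was not tested. The contrasts of classical with non-classical markers (-1.96 with the median of members, adjusted permutation p = 0.0543) and of monocyte with tissue macrophage markers (0.33 with members of a mean TPM of 1 or more, adjusted permutation p = 0.899, since 1 gene is left) no longer passed under those settings. Monocyte minus NK cell markers ranged from -0.72 to 0.21 with each library left out and was above 0 only without library 3. The other 7 contrasts kept their direction and their side of the threshold, but with members of a mean TPM of 1 or more some were far smaller: monocyte minus erythroid markers 0.16 (adjusted permutation p = 0.899), T cell 3.36, neutrophil 3.84, platelet 3.80 and dendritic cell markers 4.21. The coefficient of variation was 0.669 with the M4 tables, 0.796 without a count filter, 0.422 with a summed count of 100 or more and 0.662 to 0.717 with each library left out, so it rests largely on genes of few counts. Of the named genes, limma gave 91 the same call, 10 a call they lacked and 11 none where there was one, and DESeq2 gave 106 the same call and 6 one they lacked. For the list differences between libraries, alternatives chosen after the data were seen (M4 tables, tables made from the reads, a pseudocount of 1, correction for length and GC content) reversed none of 27 medians but moved several by over 1.5 times. With a pseudocount of 1 the neutrophil medians of library 3 against libraries 1 and 2 were -1.43 and -1.35, the basophil, eosinophil and mast cell median against library 1 -1.41 and the dendritic cell median against library 2 -0.96. With the tables made from the reads, T cell genes of library 2 against library 1 were at 0.21, classical monocyte genes of library 3 against library 2 at -0.44 and histone genes of library 3 against library 1 at 0.03. With the correction for length and GC content mitochondrially encoded genes of library 3 against library 2 were at -0.57. Members above the level numbered 152 to 195 over all lists; at 0.5 TPM the interferon-stimulated list had 8 and the basophil, eosinophil and mast cell list 7, and at 2 TPM the latter had 2, the T cell list 1 and the dendritic cell list 0. Of genes simulated at 2 TPM 29% were recovered, and of those at 0.5 TPM 18%, with every gene given the common coefficient of variation of 0.744. Genes with a summed count of 100 or more had 0.422. These shares therefore do not give the recovery of well-counted genes in these libraries. Depth was not varied apart from the spread between libraries. No paired analysis was possible because the series holds 1 group.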

Other observations

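The tests of this part were chosen after the data were seen, and the genes Hspa1a, Hspa1b, Il6, Pf4, Alas2 and Nkg7 were singled out after their values were seen. Heat shock genes differed most within the immediate early and heat shock list. Hspa1b had 1.66, 1.17 and 38.7 TPM and its near-identical neighbour Hspa1a 0.90, 0.46 and 20.8 TPM in libraries 1, 2 and 3. The cytokine Il6 had 12.8, 14.2 and 0.92 TPM. Pf4, a platelet chemokine, had 1.68, 2.23 and 19.2 TPM, and Alas2, which starts haem synthesis in red cell precursors, 19.3, 18.9 and 1.99 TPM. Nkg7, a granule protein of cytotoxic cells, had 30.4, 32.4 and 104 TPM.

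MHC class II genes were lower in library 3 than in library 1 for 7 of 7 members, with a median of -0.82 (log2, relative to the median protein-coding gene), at the 0.51 percentile of random lists, and against library 2 the median was -0.61 at the 4.04 percentile. B cell genes had medians of -0.26 and -0.44 in the same comparisons, at the percentiles 8.3 and 1.35. The difference between both lists was not tested.

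Changes of protein-coding genes from library 1 to library 3 had a Spearman correlation of 0.223 with transcript length and 0.0769 with GC content across 8292 genes, which are not independent. From library 1 to library 2 these were 0.0223 and 0.0289. Library 3 had the widest recorded fragment sizes, up to 1000 bp, against 594 bp and 491 bp for libraries 1 and 2.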
